A study of Homo sapiens with 9 samples.

How the data were processed

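RNA was measured on 9 Affymetrix arrays of human cells that had been grown out of capillary networks sprouting from adipose tissue explants of 3 individuals. The arrays fall into 3 groups of 3, namely cells never differentiated, cells taken through adipogenic differentiation and given vehicle, and differentiated cells given forskolin. Each group carries biological replicates 1, 2 and 3, and the labels do not say whether a number stands for the same individual in every group. Per the labels, 10 µg of total RNA was used for each array.

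The deposited table holds 1 log2 value per probe set and array, as made by the authors, for 70523 probe sets. Per the submitters' processing notes the values came from Affymetrix Expression Console, whose version, background correction, normalization and summarization method are not given in the sources used here. That the scale is log2 follows from the values, which ran from 1.01 to 14.1. The array medians lay between 4.63 and 4.73 and the quartiles were nearly but not exactly alike. The number of arrays limits the precision.

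Probe sets were named with the probe table that comes with the reference, which lists 25324 of them. A probe set was kept when it had exactly 1 gene symbol, which held for 23781; another 1543 had several symbols and 45199 had no name in the table. The gene ID of 21497 of the kept probe sets was found in the reference gene table, and 0 symbols had to be updated. Because the cells come from donors, 231 probe sets were left out: XIST, Y-linked genes, HLA genes and a fixed list of genes often deleted or highly polymorphic in people. PCSK1 was on gene lists but not in the probe table, so it was not analysed here. Each of the 22368 genes was represented by its probe set with the highest mean over all arrays. A gene was tested if it exceeded the 25th percentile of all probe sets on at least 3 of the 9 arrays, which kept 19676 genes.

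Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default settings on the log2 values, with all 9 arrays in 1 fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and all tests were two-sided. The 3 comparisons were differentiated minus undifferentiated, forskolin minus differentiated and forskolin minus undifferentiated. The groups, the tests, the gene lists and the rule for named genes were fixed before the data were examined.

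The replicate numbers were then checked for pairing, before any calls were compared. After removal of the group means, the 9 pairs of arrays with the same number correlated at 0.301 to 0.684, with a median of 0.613, and the 18 pairs with different numbers at -0.625 to 0.254, with a median of -0.344. These correlations are across genes within pairs of arrays, and genes are not independent replicates. Every same-numbered pair was above 0.1, so the numbers were treated as pairing the arrays, on the evidence of the values and not of the labels. For calls and counts of calls from all 9 arrays that the report gives, the value with the replicate number as a fixed block stands beside the value without it where the call differs or the count differs by more than 1.5 times.

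Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists of a comparison; camera with an estimated correlation and fry were run beside it. The lists, recalled from general knowledge, hold 793 distinct genes, of which 692 were measured. They cover adipocyte identity and lipid droplet, fatty acid and triglyceride synthesis, lipolysis and fatty acid oxidation, thermogenic and beige or brown markers, creatine, calcium and glycerol cycling, respiratory chain subunits encoded in the nucleus, citric acid cycle and pyruvate use, cAMP-responsive genes, adrenergic and cAMP signalling machinery, secreted factors named by the study, neuropeptides and prohormone processing, adipokines and metabolic hormones, glucocorticoid-responsive genes, fibrillar collagen and matrix, basement membrane and adipocyte matrix, smooth muscle, pericyte and contractile, endothelial, mesenchymal progenitor and fibroblast, macrophage and other leukocyte, epithelial and mesothelial, neural and Schwann, skeletal muscle, cell cycle, cholesterol synthesis and uptake, inflammatory cytokines and NF-kB, interferon-responsive genes, angiogenic factors, TGF-beta and BMP signalling, Wnt signalling, heat shock and stress response, and ribosomal proteins. Some genes stand on several lists.

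Named genes were the 12 highest and 12 lowest fold changes per comparison among called genes whose values did not overlap between the groups and whose brighter group lay above the median of all probe sets, 4.69. Unnamed loci, small RNA genes and antisense genes were outside that rule. Another 12 genes were named in advance whatever their values, and each list gave up to 4 called members, or up to 2 with the greatest change where none was called. The same rule applied to the fit with the replicate block, and all its calls in the differentiation comparison, were added after the values had been seen.

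Fits were tested on simulated data with 50 genes changed at each size. Normal noise was drawn separately for each gene, with means and variances taken from these arrays and a shared part per replicate number. It held no correlation between genes and no difference in noise between arrays, so the shares below hold for that setting. For forskolin against vehicle, a change of 0.5 on the log2 scale was recovered in 42% of genes, of 1 in 82%, of 2 in 94% and of 4 in 98%, with 2 false calls among 160. With the replicate block the shares were 56%, 92%, 98% and 100%, with 10 false calls among 183.

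Alternatives set in advance were the replicate block, a random block, only the 6 arrays compared, repeated quantile normalization, centring on array medians, no dim filter, a dim filter at the 50th percentile, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, an added minimum absolute log2 change of 1, an adjusted p under 0.01, and leaving out each array and each replicate number in turn. The block combined with 6 arrays, or with a number left out, was added after seeing the data. No genome build was used, so no coordinates are given.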

Results

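The study followed cells derived from human adipose capillary networks through 3 states, each measured on 3 arrays labelled as biological replicates. Explants of adipose tissue from 3 individuals were cultured in a hydrogel under conditions that favour vessel growth, and the cells of the emerging capillaries were then expanded on plastic. Undifferentiated cells were compared with cells after adipogenic differentiation, a programme, named MDI in the labels, that turns progenitors into fat cells. No culture time is known here for the undifferentiated cells, so differentiation and time in culture cannot be told apart in comparisons with them. The differentiated cells had received either vehicle or 50 µM forskolin for 7 days, starting after 12 days. Forskolin activates adenylate cyclase, the enzyme that makes cAMP, the messenger of adrenergic stimulation. Each array holds 70523 probe sets, with medians of 4.72, 4.71 and 4.63 (log2) on the undifferentiated, 4.73, 4.7 and 4.68 on the differentiated and 4.66, 4.71 and 4.69 on the forskolin arrays. Values below are log2 signal, shown as mean ± SD with n = 3 arrays, and fold changes are log2 with their SE. Limma p-values without the block measure the spread between biological replicates from 3 individuals, and the labels do not say that a number is one individual. With the block they measure the spread left once differences between replicate numbers are removed. Camera p-values compare the genes of a list with all others and depend on the preset or estimated correlation between genes.

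Adipogenic differentiation raised FABP4, the fatty acid carrier of adipocytes. Its signal rose from 2.99 ± 0.17 in undifferentiated cells to 9.83 ± 0.67 after differentiation, a fold change of at least 6.84 ± 0.42 (adjusted p = 0.0028). The fold change is a lower bound because the undifferentiated level lies below the 25th percentile of those arrays, 3.39, 3.35 and 3.29. ADIPOQ, which encodes the adipocyte hormone adiponectin, went from 4.69 ± 0.23 to 8.98 ± 0.78, and its change of 4.29 passed with the replicate block (adjusted p = 0.0358) but not without it (adjusted p = 0.390). AOC3, an amine oxidase of the adipocyte surface, changed by 2.93 (adjusted p = 0.0107 with the block, 0.755 without) and LBP, the lipopolysaccharide-binding protein, by 1.66 (adjusted p = 0.013 with the block, 1 without). All 3 pairs of same-numbered arrays moved upward for each of these genes, which follows wherever the values of the 2 groups did not overlap.

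FABP4 was the 1 gene of 19676 that passed without the block, against 771 at an unadjusted p under 0.05. With the block 7 genes rose and 1 fell, 8 in all. The others, chosen after their values were seen, were the small nucleolar RNAs SNORA47 (1.87), SNORA75 (0.80) and SNORD126 (0.75), and VCAN-AS1, annotated as antisense to VCAN, which fell by 1.47. Among genes named in advance that passed in neither fit, PLIN1, the coat protein of lipid droplets, had a change of 2.31 ± 0.62, PPARG, the master regulator of adipogenesis, 1.04 ± 0.62, LEP, which encodes leptin, 0.82 ± 0.60 and CIDEA 0.07 ± 0.15. The count was 91 without undifferentiated replicate 1, 2 without differentiated replicate 1 and 0 without undifferentiated replicate 3, where FABP4 had an adjusted p of 0.0558.

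Of 31 gene lists, 7 shifted with differentiation by camera, and none of these calls held with an estimated correlation, where 3 lists had an unadjusted p under 0.05; fry called 1, the interferon list. The adipocyte identity and lipid droplet list moved up, with a median of 0.93 over 26 measured members (adjusted p = 6.97e-15; adjusted p = 0.502 with an estimated correlation). Over all genes 1 of its members rose and 25 did not pass, 2 rose with the block, and 3 rose adjusted over the list alone, 16 with the block. Genes of fatty acid and triglyceride synthesis had a median change of 0.51 (adjusted p = 4.94e-07; adjusted p = 0.705 with an estimated correlation), with THRSP, a regulator of lipogenesis, at 2.90 ± 1.04 and GPAM, the first acyltransferase of triglyceride synthesis, at 2.22 ± 0.75. Those of lipolysis and fatty acid oxidation had a median of 0.30 (adjusted p = 7.92e-06; adjusted p = 0.705 with an estimated correlation), with G0S2, an inhibitor of adipose triglyceride lipase, at 1.39 ± 0.39. In limma no member of either list passed over all genes in either fit, with 4 and 2 at an unadjusted p under 0.05, or 11 and 5 with the block. Adjusted over the list alone none passed without the block, and 3 and 1 rose with it.

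Interferon-responsive genes moved the other way, with a median change of -0.27 over 24 members (adjusted p = 1.24e-15; adjusted p = 0.0522 with an estimated correlation). No member passed over all genes in limma, 11 were lower at an unadjusted p under 0.05, and 6 fell adjusted over the list alone, 12 with the block. IFI6, an interferon-induced mitochondrial protein, was at 8.84 ± 0.44 against 10.33 ± 0.12. TGF-beta and BMP signalling (median -0.11, adjusted p = 0.00513; adjusted p = 0.667 with an estimated correlation) and mesenchymal progenitor and fibroblast genes (median -0.10, adjusted p = 0.0217; adjusted p = 0.705 with an estimated correlation) shifted down. Basement membrane and adipocyte matrix genes shifted up (median 0.09, adjusted p = 0.0237; adjusted p = 0.502 with an estimated correlation), with medians of -0.01, 0.06 and 0.21 in the same-numbered pairs. The block added the heat shock, cholesterol and citric acid cycle lists (adjusted p = 0.025 for each; adjusted p = 0.608, 0.721 and 0.721 with an estimated correlation) and creatine, calcium and glycerol cycling (adjusted p = 0.0305; adjusted p = 0.498 with an estimated correlation), 11 lists in all. Of these added lists heat shock shifted down and the others up. The cholesterol list had medians of -0.04, 0.46 and 0.03 in the same-numbered pairs. Its call rests mainly on number 2. With the block 5 progenitor genes and 1 TGF-beta gene fell, and 1 gene each of the basement membrane and creatine lists rose, adjusted over the list alone. By fry with the block the interferon list did not pass (adjusted p = 0.0637).

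Some of these list calls were lost and others gained when 1 array was left out, which also leaves fewer arrays for the test. Lipolysis and fatty acid oxidation lost its call without undifferentiated replicate 1 (camera adjusted p = 0.0897, list mean 0.26). Fatty acid and triglyceride synthesis lost its call without differentiated replicate 2 (camera adjusted p = 0.0757, list mean 0.36). Against the mean of all arrays the synthesis list stood at -0.29, 0.83 and -0.08 on differentiated replicates 1, 2 and 3. The TGF-beta list lost its call without undifferentiated replicate 1, undifferentiated replicate 3 or differentiated replicate 1 (camera adjusted p = 0.0610, 0.164 and 0.0518). Its mean change stayed negative in these fits, at -0.19, -0.12 and -0.12. Progenitor and basement membrane genes lost their calls without undifferentiated replicate 1 (camera adjusted p = 0.0849 and 0.164), undifferentiated replicate 3 (0.364 and 0.164) or differentiated replicate 2 (0.0776 and 0.110). In these fits, in that order, the progenitor mean was -0.17, -0.11 and -0.10 and the basement membrane mean 0.13, 0.13 and 0.10, so both kept their direction. The number of shifted lists was 4 without undifferentiated replicate 1, 12 without undifferentiated replicate 2, 14 without differentiated replicate 1 and 11 without forskolin replicate 2. Gained calls included cholesterol synthesis (adjusted p = 8.33e-06) and inflammatory genes (downward, 0.00362) without differentiated replicate 1, respiratory chain (0.000426) and citric acid cycle (0.0031) without undifferentiated replicate 3, and fibrillar collagen (downward, 0.00607) without undifferentiated replicate 2. The thermogenic, creatine, heat shock, contractile, skeletal muscle, neuropeptide, cell cycle, Wnt and ribosomal lists also gained one without some array.

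Forskolin raised PDK4, PPARGC1A, IL33 and PENK and lowered CEMIP and ITGA8 in differentiated cells. PDK4, the kinase that shuts pyruvate out of the citric acid cycle, rose from 5.39 ± 0.87 with vehicle to 9.12 ± 0.98, a change of 3.73 ± 0.53 (adjusted p = 0.0369). PPARGC1A, the coactivator that drives mitochondrial biogenesis, rose by 2.01 ± 0.31 (adjusted p = 0.0439), and IL33, a cytokine of the interleukin-1 family, by 2.66 ± 0.26 (adjusted p = 0.00797). PENK, the precursor of the enkephalin peptides, rose from 5.92 ± 0.08 to 6.57 ± 0.09 (adjusted p = 0.0377). CEMIP, a hyaluronan-degrading protein, fell by 2.41 ± 0.15 (adjusted p = 0.00175) and ITGA8, an integrin of contractile mesenchymal cells, fell by 2.92 ± 0.41 (adjusted p = 0.0344). Among these genes CEMIP alone was called whichever array was left out. In each of these genes all 3 same-numbered pairs moved in the stated direction. For genes named by the rule of non-overlapping values this had to be so, and it adds no support.

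**Figure D1:**
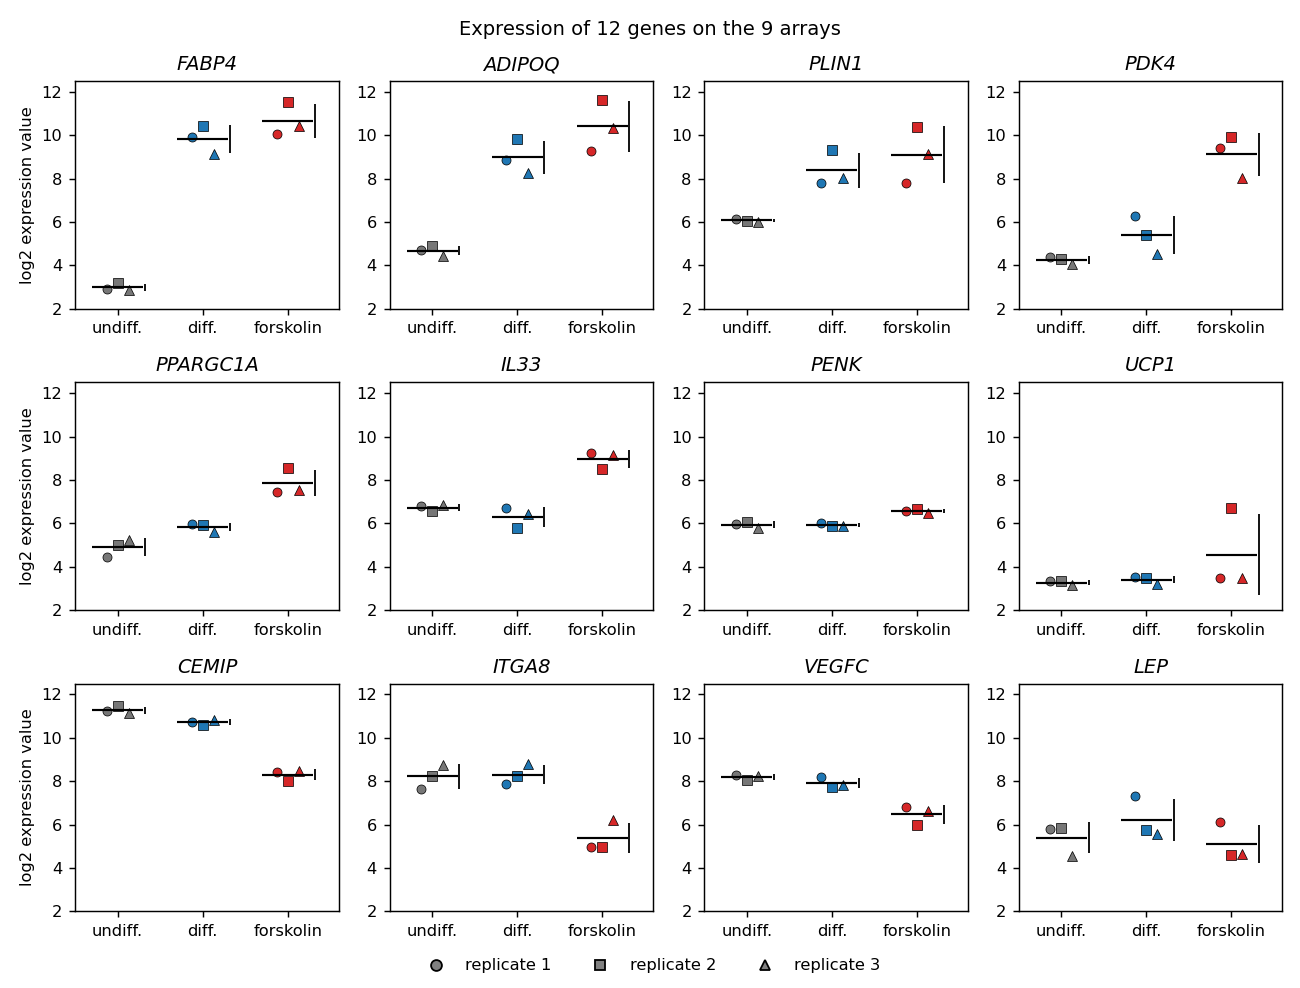
Log2 signal (vertical axis) of 12 genes in undifferentiated cells, differentiated cells with vehicle and differentiated cells with forskolin (horizontal axis); each point is an array, its marker gives the replicate number, the horizontal line is the mean and the vertical bar ± 1 SD, n = 3. FABP4 stands at 2.99 before and 9.83 after differentiation, and UCP1 stands high on forskolin replicate 2 alone, at 6.70 against 3.14 to 3.52 on the other 8 arrays.

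In all, 39 genes rose and 31 fell with forskolin, and with the replicate block 154 rose and 163 fell, including all 70 of the former. Further genes that rose were CNTNAP4 (2.6), CHMP1B (2.24), PITPNC1 (2.08), CHL1 (2.00), ANXA10 (1.96), PDE3A (1.94), CRISPLD2 (1.90), SFRP4 (1.85), a secreted Wnt antagonist, and HPD (1.83), an enzyme of tyrosine breakdown. Those that fell were KRTAP1-5 (-2.43), ATP8B1 (-2.01), NAV3 (-1.59), FRMD6 (-1.50), VEGFC (-1.44), FMN2 (-1.38), UACA (-1.36), SERPINB7 (-1.35), ADAMTS1 (-1.33) and SCG5 (-1.29). With the block alone, SPON1 (2.54), AADAC (2.40), TFPI2 (2.19) and the growth factor IGF1 (2.07) rose, while ANKRD1 (-2.33), PSG5 (-1.63), LMO7 (-1.57), MSC (-1.55), CCN2 (-1.54), USP53 (-1.52) and MICAL2 (-1.51) fell; these were named after the values had been seen. Leaving out 1 array moved the count of 70 to 32 without undifferentiated replicate 2 or 3, 25 without differentiated replicate 1, 13 without differentiated replicate 2 or 3, and 42, 28 and 46 without forskolin replicate 1, 2 and 3. Of the 28 named genes, ANXA10, ATP8B1, CEMIP, CHMP1B and NAV3 were called whichever array was left out; IL33 was called in 8 of those 9 fits, ITGA8 in 2, and PDK4, PENK and PPARGC1A in 1 each, with adjusted p up to 0.0512, 0.178, 0.178, 0.204 and 0.222. SCG5 was called in 0 of them (adjusted p = 0.0519 to 0.178). With replicate number 1, 2 or 3 left out, 12, 3 and 0 of the 28 named calls were kept.

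cAMP-responsive genes shifted up together with forskolin, with a median change of 0.32 over 37 members (adjusted p = 1.07e-14; adjusted p = 0.00252 with an estimated correlation, 0.0297 with the block as well). Over all genes 5 rose, 1 fell and 31 did not pass, 8 rose with the block, and 11 rose and 1 fell adjusted over the list alone, 17 and 1 with the block. PDE3A and PDE7B, phosphodiesterases that break down cyclic nucleotides, rose by 1.94 and 1.75, and CITED2, a transcriptional coregulator, fell by 1.25. In the adrenergic and cAMP signalling machinery, whose median was -0.02 and mean 0.05 over 34 members, limma called none over all genes, with 4 higher and 1 lower at an unadjusted p under 0.05, and 1 rose and 1 fell adjusted over the list alone, 2 and 1 with the block. PRKAR1A, a regulatory subunit of protein kinase A, rose by 0.71 with the block (adjusted p = 0.0146).

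Genes of mitochondrial fuel use shifted up with forskolin. Nuclear-encoded respiratory chain subunits had a median change of 0.26 over 57 members (adjusted p = 1.88e-22; adjusted p = 0.230 with an estimated correlation), and genes of the citric acid cycle and pyruvate use 0.42 over 19 (adjusted p = 6.41e-12; adjusted p = 0.317 with an estimated correlation). No member of either passed over all genes in limma without the block, with 19 and 5 higher at an unadjusted p under 0.05. Adjusted over the list alone 0 and 1 rose without the block, and 25 and 11 with it. Over all genes with the block ATP5F1B, a subunit of ATP synthase, rose by 0.64 (adjusted p = 0.0338). Lipolysis and fatty acid oxidation genes shifted up by a median of 0.39 (adjusted p = 9.44e-10; adjusted p = 0.413 with an estimated correlation), and PDK4 was the 1 of 27 that rose, both over all genes and adjusted over the list alone. On these lists forskolin replicate 2 stood above the other forskolin arrays, by a median of 0.27 for respiratory chain, 0.64 for citric acid cycle and 0.79 for lipolysis genes. Without that array all of them kept their calls.

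The adipocyte list had a median change of 0.56 with forskolin over 26 members (camera adjusted p = 3.7e-05, and 0.536 with an estimated correlation). This call was lost without forskolin replicate 2 (camera adjusted p = 0.131, list mean 0.12). Against the mean of all arrays the list stood at -0.04, 1.81 and 0.62 on forskolin replicates 1, 2 and 3. On differentiated replicates 1, 2 and 3 it stood at -0.12, 0.65 and -0.05. Limma called none of its members over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05; ADIPOQ had 1.43 ± 0.58, LPL 1.45 ± 0.79, FABP4 0.84 ± 0.42, PLIN1 0.73 ± 0.62 and PPARG 0.51 ± 0.62. Thermogenic and beige or brown markers shifted up (adjusted p = 0.0165; adjusted p = 0.536 with an estimated correlation), with a mean of 0.34 beside a median of 0.02 over 30 members, and lost that call too without forskolin replicate 2 (adjusted p = 0.131). The medians in the same-numbered pairs were -0.05, 0.08 and 0.03. PDK4 and PPARGC1A were the 2 members that rose over all genes, 4 did with the block, and 3 rose and 1 fell adjusted over the list alone, 5 and 2 with the block. UCP1, the uncoupling protein of brown fat, had a change of 1.14 ± 0.75 (adjusted p = 1), with 4.54 ± 1.86 against 3.40 ± 0.16, since forskolin replicate 2 read 6.70 and the other 8 arrays 3.14 to 3.52. CIDEA had 0.25 ± 0.15, and DIO2, which activates thyroid hormone, rose by 1.10 with the block (adjusted p = 0.0354) but not without it (adjusted p = 0.314).

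**Figure D2:**
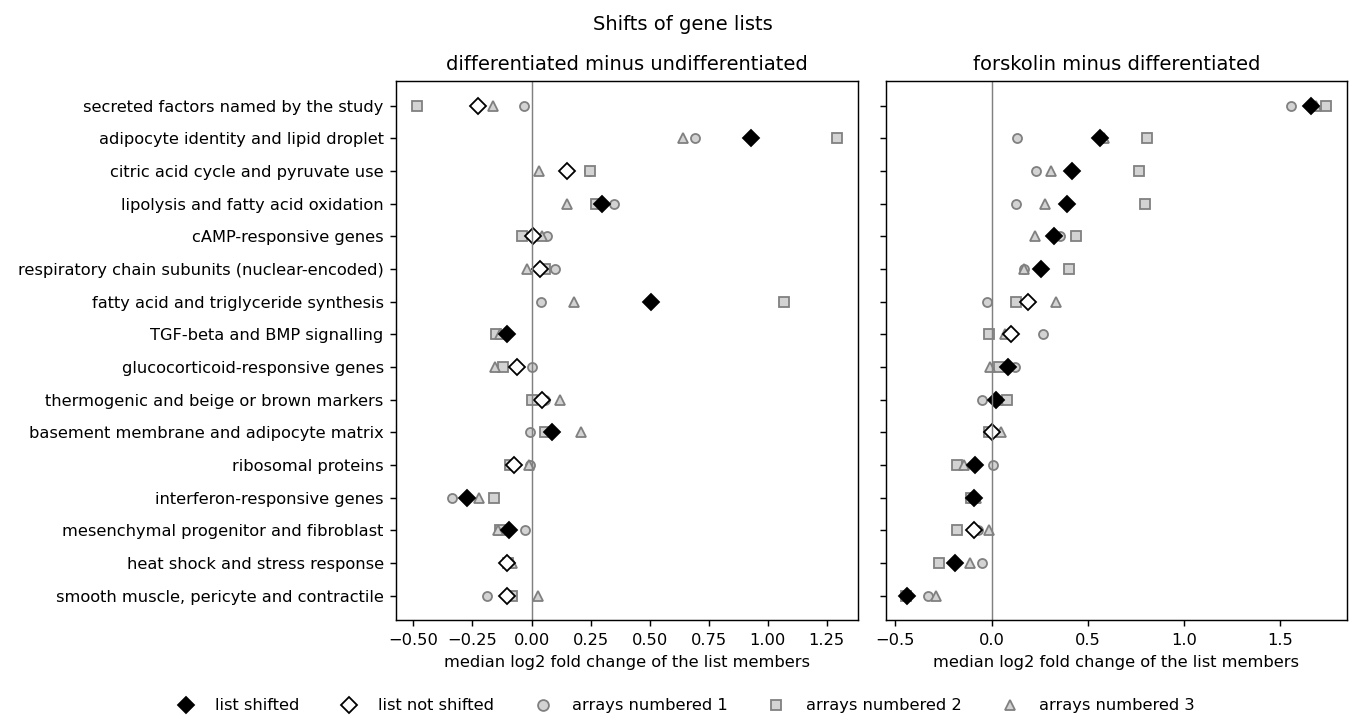
Median log2 fold change (horizontal axis) of the members of 16 gene lists (vertical axis) for differentiation and for forskolin against vehicle, on separate scales; black diamonds are lists shifted by camera, other diamonds are not, and grey points are the medians within each pair of same-numbered arrays. Adipocyte genes stand at 0.93 with differentiation and 0.56 with forskolin, contractile genes at -0.44 with forskolin.

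Contractile genes went down with forskolin. The smooth muscle, pericyte and contractile list had a median change of -0.44 over 23 members (adjusted p = 4.09e-07; adjusted p = 0.184 with an estimated correlation), with TPM1, a tropomyosin of stress fibres, at -1.06 ± 0.21. In limma none passed over all genes, 3 were higher and 12 lower at an unadjusted p under 0.05, and 3 rose and 10 fell adjusted over the list alone. With the block 1 rose and 2 fell, the former being ABCC9, a subunit of potassium channels in mural cells (1.30, adjusted p = 0.0062). Heat shock and stress response genes had a median of -0.19 (adjusted p = 0.000676; adjusted p = 0.203 with an estimated correlation), interferon-responsive genes -0.09 (adjusted p = 0.0131; adjusted p = 0.413 with an estimated correlation) and ribosomal proteins -0.09 (adjusted p = 0.0365; adjusted p = 0.644 with an estimated correlation). None of their members passed in limma over all genes. At an unadjusted p under 0.05, 1 heat shock gene was higher and 6 were lower, 6 interferon-responsive genes were lower and 0 ribosomal genes passed; adjusted over the list alone, 5 interferon-responsive genes fell, and 4 heat shock genes did with the block. Over all genes with the block 2 interferon-responsive genes fell, among them IFIT2 (-0.58, adjusted p = 0.0328). The ribosomal call was lost without differentiated replicate 3 (adjusted p = 0.306) or forskolin replicate 2 (adjusted p = 0.540), and pair 1 had a median of 0.01.

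Secreted signals moved in both directions. IL33 and PENK were the 2 measured members of the secreted factors named by the study, and both rose over all genes and adjusted over the list alone (camera adjusted p = 4.19e-08; adjusted p = 0.0174 with an estimated correlation, but 0.219 with the block as well). The study chose them on these samples, so the list is not independent evidence. Among neuropeptides and prohormone processing PENK rose and SCG5, a chaperone of prohormone convertase, fell while all arrays were kept, 1 up and 1 down of 18 also when adjusted over the list alone. Adipokines and metabolic hormones had 0 of 23 called over all genes in limma, 3 higher and 1 lower at an unadjusted p under 0.05, and 1 up and 1 down adjusted over the list alone, 6 and 3 with the block, with LEP at 5.10 ± 0.87 against 6.21 ± 0.97 (-1.11 ± 0.60); over all genes with the block 1 rose, IGF1, and 1 fell. The adipokine list shifted up without differentiated replicate 1 (adjusted p = 0.0298). Of 26 inflammatory cytokine and NF-kB genes IL33 rose, also adjusted over the list alone; with the block 5 rose and 2 fell over all genes, and 7 rose and 4 fell adjusted over the list alone. That list shifted up with the block (adjusted p = 0.0052; adjusted p = 0.254 with an estimated correlation) but not without it (adjusted p = 0.225), where it passed if differentiated replicate 1, forskolin replicate 2 or forskolin replicate 3 was left out (adjusted p = 0.00123, 0.0122 and 0.0333). Its medians in the same-numbered pairs were 0.31, -0.01 and 0.08. Against the mean of all arrays it stood at 0.65, 0.41 and 0.93 on the number 1 arrays of the 3 groups and at -0.35 to -0.19 on the others. Of 25 glucocorticoid-responsive genes PDK4 and CRISPLD2 rose, also adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.04998; adjusted p = 0.317 with an estimated correlation). That call was lost without any 1 of the 3 undifferentiated arrays (camera adjusted p = 0.110, 0.0658 and 0.122), differentiated replicate 2 or 3 (0.0726 and 0.0823) or forskolin replicate 1 or 2 (0.239 and 0.0525). The undifferentiated arrays do not enter this change, and the list mean was 0.33 without each of them. It was 0.22 to 0.35 in the other fits that lost the call.

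On matrix and signalling lists few genes were called over all genes without the block. In the basement membrane list NID1, a linker of laminin and collagen, rose by 0.70 and ADAMTS1, a matrix protease, fell by 1.33, as they did adjusted over the list alone, where 2 rose and 1 fell with the block, with a median of -0.00 and a mean of 0.03. VEGFC, the growth factor of lymphatic vessels, was the 1 of 24 angiogenic factors that fell, also adjusted over the list alone (median -0.01, mean 0.01), and SFRP4 the 1 of 28 Wnt genes that rose, likewise adjusted over the list alone (median -0.00, mean 0.14). With the block 1 angiogenic factor rose and 1 fell over all genes, and 7 rose and 5 fell adjusted over the list alone; 3 Wnt genes rose either way. TGF-beta and BMP signalling had 0 of 28 called over all genes by limma, 3 higher and 4 lower at an unadjusted p under 0.05, and 1 up and 4 down adjusted over the list alone, 5 and 5 with the block. Mesenchymal progenitor and fibroblast genes had 0 of 28, 4 higher and 7 lower at an unadjusted p under 0.05, and 2 up and 4 down adjusted over the list alone, 5 and 8 with the block. Over all genes with the block 3 progenitor genes rose and 2 fell, among the latter DPP4, a surface marker of progenitors (-1.48, adjusted p = 0.00887), and 1 TGF-beta gene rose and 2 fell. Fibrillar collagen and matrix genes had 0 of 32 called in limma, 2 higher and 6 lower at an unadjusted p under 0.05, and none adjusted over the list alone, with POSTN at -1.66 ± 0.57. With the block 1 fell over all genes, CCN2, and 1 rose and 4 fell adjusted over the list alone. Leaving out 1 array gave some of these lists a call: TGF-beta shifted up without forskolin replicate 2 (adjusted p = 0.0261), and Wnt without differentiated replicate 1 or forskolin replicate 2 (adjusted p = 0.0330 and 0.0290). Progenitor genes shifted down without forskolin replicate 1 or 3 (adjusted p = 0.0219 and 0.0151), and fibrillar collagen genes without forskolin replicate 1 (adjusted p = 0.0392).

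Markers of other cell types gave few calls with forskolin. Limma called none over all genes among endothelial (18 measured, median -0.05), macrophage and other leukocyte (17, -0.07), epithelial and mesothelial (16, -0.07), neural and Schwann (10, -0.03 with a mean of 0.03) and skeletal muscle genes (16, -0.06). At an unadjusted p under 0.05 there were 0, 1, 1, 1 and 0, and adjusted over the list alone 1 neural gene rose, SNAP25 with 0.47 (adjusted p = 0.3 over all genes, 0.0151 with the block). Nor did limma call members on the cell cycle (31, median -0.06), cholesterol synthesis and uptake (20, 0.12), fatty acid and triglyceride synthesis (22, 0.19) or creatine, calcium and glycerol cycling lists (14, 0.05), with 1, 1, 1 and 1 at an unadjusted p under 0.05 and none adjusted over the list alone. None of these lists shifted by camera in either fit. Single arrays changed this for some: without differentiated replicate 1 the cell cycle list shifted up (adjusted p = 0.0245), and without forskolin replicate 1 it shifted down (adjusted p = 0.0182). Without forskolin replicate 1 the lists of fatty acid synthesis and cholesterol synthesis (adjusted p = 1.73e-05 for both), creatine cycling (0.0404) and skeletal muscle (0.0219) also passed; so did fatty acid synthesis without differentiated replicate 2 (6.56e-08) or forskolin replicate 3 (0.0434), cholesterol synthesis without differentiated replicate 2 (0.000463) and skeletal muscle without differentiated replicate 2 or 3 (0.0455 and 0.046).

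Compared with cells never differentiated, forskolin-treated cells were higher in FABP4, ADIPOQ, PDK4 and PPARGC1A. FABP4 was higher by at least 7.68 ± 0.42 (adjusted p = 0.000549), ADIPOQ by 5.72 ± 0.58 (adjusted p = 0.00511), PDK4 by 4.88 ± 0.53 (adjusted p = 0.00698) and PPARGC1A by 2.95 ± 0.31 (adjusted p = 0.00573). PRKAR2B, a protein kinase A subunit abundant in fat, rose by 3.69, LBP by 3.59, AOC3 by 3.23, RASD1 by 2.67, EREG by 2.16 and NAMPT, which makes an NAD precursor, by 1.80. CEMIP (-2.97), ITGA8 (-2.84), KRTAP1-5 (-2.68), LOXL4 (-2.39), DPP4 (-2.26), SOD3 (-2.08), VEGFC (-1.72), CNN2 (-1.17) and HSPB1 (-1.01) fell, as did IFIT1 (-1.06), IFIT2, IFIT3 and XAF1 (-1.01 each), antiviral genes of the interferon response. The change of IFIT1 is a bound too, since its level with forskolin, 2.88 ± 0.20, lies below the 25th percentile of those arrays, 3.40, 3.35 and 3.33. The pseudogenes FABP5P7 (3.89) and FABP5P1 (3.62) also passed; whether their probe sets read FABP5, whose sequence they share, was not tested. Of the 46 named calls 12 were kept whichever array was left out, among them FABP4, ADIPOQ, PPARGC1A and CEMIP. PDK4 was called in 8 of those 9 fits, LBP in 6, EREG in 4, AOC3 in 3 and PRKAR2B in 1.

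In that comparison 78 genes rose and 116 fell, and with the block 575 and 721. The count of 194 became 778, 32 and 85 without undifferentiated replicate 1, 2 and 3, 111 and 115 without differentiated replicate 2 and 3, and 93 and 129 without forskolin replicate 2 and 3. By camera 16 lists shifted, 11 up and 5 down. With an estimated correlation 3 kept their call, namely cAMP-responsive genes (adjusted p = 0.00896), interferon-responsive genes (adjusted p = 0.0465) and the secreted factors named by the study (adjusted p = 0.0465). With the block as well, each of them lost it (adjusted p = 0.0669, 0.114 and 0.213). Adipocyte genes had a median of 1.45, 2 of 26 rose over all genes, 16 with the block, and 15 adjusted over the list alone (adjusted p = 7.96e-14; adjusted p = 0.211 with an estimated correlation). Lipolysis and fatty acid oxidation genes had a median of 0.69, 1 of 27 rose over all genes, 12 with the block, and 16 adjusted over the list alone (adjusted p = 8.68e-13; adjusted p = 0.249 with an estimated correlation). Interferon-responsive genes had a median of -0.30, and 5 fell over all genes, 9 with the block, and 10 adjusted over the list alone, 15 with the block. Leaving out 1 array ended the calls of the basement membrane, cholesterol, thermogenic, creatine, progenitor or ribosomal lists (adjusted p up to 0.463). It gave one to the adipokine, inflammatory, fibrillar collagen or endothelial lists (adjusted p down to 0.0123).

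No gene was called in both differentiation and forskolin against vehicle without the block, with 127 at an unadjusted p under 0.05 in both. With the block 2 were: LBP, which rose in both (1 shared gene, 0.0548 if the lists were independent), and VCAN-AS1, which fell with differentiation and rose with forskolin (1 shared, 0.00783 if independent). Both comparisons use the 3 differentiated arrays, and 50 simulations with unchanged groups shared 0 genes. That sets no yardstick, since they held 1 call at most in a comparison. Across 19676 genes, which are not independent replicates, the fold changes correlated at 0.157, against -0.5 when unchanged groups share these arrays, and had the same sign in 46.6% against 33.4%. The covariance was 0.00687 against a simulated -0.0159, a difference of 0.0228, or of 0.0144 with the spread of the block. The 3 shared arrays cannot be split so that each part keeps 2. They enter the comparisons with opposite signs, so part of the overlap in opposite directions may come from them, and the positive correlation does not. Without undifferentiated replicate 1 the count was 2.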

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

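Fits that combined the replicate block with 6 arrays or with a number left out were chosen after seeing the data; the other alternatives were planned. Named genes kept direction and status, called in both fits or in neither, in 2354 of the combinations of gene and left-out array or number. They lost the call in 423, gained one in 46 and turned direction without a call in 9. Under the other alternatives these were 2826, 190, 268 and 7. For lists they were 908, 48, 79 and 79 with arrays left out, where 2 also turned with a call, and 1260, 88, 75 and 65 otherwise. The kept counts include genes and lists never called, so losses are a larger share of the calls themselves. Of 28 named calls for forskolin against vehicle, 5 held whichever array was left out, and of 46 for forskolin against undifferentiated cells, 12 did. Differentiation, forskolin against vehicle, and forskolin against undifferentiated cells are given in that order below, from main counts of 1, 70 and 194 genes and 7, 12 and 16 lists, and from 0 genes shared by the first 2 comparisons. Counts not given moved by no more than 1.5 times. The cause was not tested except where stated.

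With the replicate block 8, 317 and 1296 genes and 11 lists of the first comparison passed, and 2 genes were shared; the median residual variance was 0.0105 with the block and 0.0176 without it. Beyond the calls named in the report, the block changed list calls in the third comparison alone, where adipokines (adjusted p = 0.031; adjusted p = 0.252 with an estimated correlation) and inflammatory genes (adjusted p = 0.0204; adjusted p = 0.238 with an estimated correlation) passed. It ended no call of a gene, or of a list by camera with the preset correlation. With the block and an estimated correlation 0, 1 and 0 lists kept their call, and the secreted factors (adjusted p = 0.219 and 0.213 in the forskolin comparisons), cAMP-responsive (0.0669) and interferon-responsive genes (0.114, both in the third) lost it; by fry, which called 0, 3 and 13 lists with the block, the interferon list lost it for differentiation (0.0637) and the contractile list for forskolin against vehicle (0.101). A random block gave 2, 179 and 822 genes. With only the 6 arrays compared, which leaves fewer degrees of freedom, 20 and 48 genes passed in the forskolin comparisons and 11 lists for differentiation. Quantile normalization and the dim filter at the 50th percentile each gave 2 genes in the first comparison, and centring 11 lists. Array weights gave 6230, 882 and 9481 genes, 10 lists for forskolin against undifferentiated cells and 358 shared genes. Undifferentiated replicate 2 then weighed 34.1, against 0.20 and 0.17 for undifferentiated replicates 1 and 3. In comparisons with undifferentiated cells the mean of that group thus rests mainly on 1 array. The fold changes of forskolin against vehicle, with 882 genes, do not use that array. In that comparison forskolin replicates 1, 2 and 3 weighed 0.35, 0.56 and 3.89, and the differentiated ones 0.32, 2.43 and 1.43. A minimum log2 change of 1 left 43 and 105 genes in the forskolin comparisons, and an adjusted p under 0.01 left 16 and 50. Camera with an estimated correlation kept 0, 2 and 3 lists, and fry called 1, 3 and 8.

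Leaving out an array or a replicate number, which also leaves fewer arrays, gave 0 to 109 genes and 4 to 14 lists for differentiation, 0 to 80 genes and 9 to 18 lists for forskolin against vehicle, 0 to 1029 genes and 12 to 17 lists for the third comparison, and 0 to 4 shared genes. The cell cycle list turned in both of the first comparisons without differentiated replicate 1, to a mean of -0.0818 for differentiation (adjusted p = 0.0299) and of 0.0623 for forskolin against vehicle (adjusted p = 0.0245); with each array or number left out in turn its mean ran from -0.0818 to 0.0825 and from -0.12 to 0.0623. With the replicate block and number 1 left out the gene counts were 351, 298 and 2169, with 37 shared; with number 2 left out they were 0, 24 and 101, with 16 lists for differentiation; with number 3 left out they were 0, 0 and 35. The block on 6 arrays gave 5 genes and 14 lists for differentiation. Signal over background limits genes near the dim threshold: without the filter 1, 69 and 178 genes passed.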

Other observations

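The test of the adipocyte list on forskolin replicate 2 and that of centred arrays with the replicate block were chosen after results were seen; the other tests were set before their results, on patterns already noticed in these arrays. The genes of the next paragraph were chosen after their values were seen.

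Single genes also differed between forskolin-treated and undifferentiated cells when the replicate block was used. PRL, which encodes prolactin, was at 8.66 ± 1.52 (SD, n = 3) in forskolin-treated and 5.29 ± 0.95 in undifferentiated cells, a log2 change of 3.38 (adjusted p = 0.00147 with the block, 0.154 without), higher in all 3 pairs of same-numbered arrays. HP, which encodes the haemoglobin-binding plasma protein haptoglobin, rose by 3.40 (adjusted p = 0.0286 with the block, 0.179 without), and LPL, the lipase that releases fatty acids from lipoproteins, by 3.86 (adjusted p = 0.011 with the block, 0.0731 without). PDE3B, a phosphodiesterase of adipocytes, rose by 3.67 and PPARG by 1.55 in the same fit (adjusted p = 0.0143 and 0.0139, 0.0611 and 0.304 without the block). SNAP25, a protein of vesicle fusion, rose by 0.60 (adjusted p = 0.00382, 0.074 without), and PLXNC1, a semaphorin receptor, fell by 1.94 (adjusted p = 0.0319, 0.187 without).

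UCP1 stood at 6.70 on forskolin replicate 2 and at 3.14 to 3.52 on the other 8 arrays. Noise of that array at dim probe sets is argued against, since 0 of 781 genes as dim as UCP1 elsewhere had as large an excess (0%). Signal of another cell type stays open. The highest of the 5 marker list medians on that array was 0.03 above the other forskolin arrays. Medians over 10 to 18 genes cannot show a small admixture, and cell types outside these lists were not tested. That replicate number 2 formed more adipocyte RNA stays open as an explanation of the reading. The adipocyte list stood 1.49 higher on that array than on the other forskolin arrays. The differentiated arrays had list medians of 0.65 for number 2 against -0.12 and -0.05. Yet differentiated replicate 2 and forskolin replicate 3, with list medians of 0.65 and 0.62, read UCP1 no higher than 3.52. More adipocyte RNA at that level thus came without a higher UCP1 reading. The list stood at 1.81 on forskolin replicate 2, a level no other array reached. Whether forskolin raises UCP1 in cells of some individuals cannot be read from 1 array and was not tested.

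A larger share of adipocytes might account for the higher adipocyte genes with forskolin. In the adipocyte list, 13 members with a differentiation change above 1 scattered around 1 common slope by a mean square of 0.733, within the simulated 95% limit of 3.93. The slope was 117% (95% interval 66.8% to 168%), so a larger share alone stays open for that list. This slope pools unlike pairs. Pair 1 changed least in each member but PPARG (0.51, 0.43 and 0.60 in pairs 1, 2 and 3), as in FABP4 (0.12, 1.11 and 1.30). For the 154 genes called higher with the block, the common slope predicted a change from the upper 95% limit of their differentiation change. The lower 95% limit of the forskolin change lay above that prediction in 93.5%, and in 79.2% at the slope's upper limit. These percentages do not decide whether a larger share alone explains those genes. The genes were picked for a high forskolin change, and the slope interval treated members as independent although they moved together within pairs. After quantile normalization 87.4% of the 317 calls with the block kept call and sign. That cannot exclude array scaling as a cause, since the array quartiles were nearly alike beforehand, which left that step little to change. Centring on array medians kept the sign of all 317 and the call of 74.1%; in the 82 that lost it the median absolute log2 change went from 0.58 to 0.57 and the median SE from 0.09 to 0.11, so these calls ended mainly through a wider spread. Without the block, centring left 49 genes against 70, and 21 of 28 named calls were kept, against 27 after quantile normalization. How far array scaling shaped these calls stays open. A direct effect of forskolin on these genes, which the design names, stays open.

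More calls were made with the replicate block, and a candidate explanation is that same-numbered arrays share an individual or a culture day. This stays open. Of 36 ways to number the arrays, 1, the true one, gave a median residual variance as low as 0.0105, but that adds no evidence: the same-numbered arrays already correlated at 0.301 or more and the others at 0.254 or less, which fixes the outcome. Individual and culture day were not separated by the design.

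A hypothesis drawn from ANKRD1 and CCN2, which fell with forskolin when the block was used, is lower expression of target genes of YAP and TEAD, transcription regulators that respond to cell tension. A list of 22 targets was written from general knowledge, 4 of them on lists used above, and 20 were measured once ANKRD1 and CCN2 were set aside. Their median change with forskolin was -0.34, with 16 of 20 negative and medians of -0.24, -0.49 and -0.32 in the same-numbered pairs, and camera with an estimated correlation gave p = 0.0225. With the block F3, ASAP1, CRIM1 and AXL fell; without it limma called 0. These values are consistent with the hypothesis, which was found and tested on the same arrays; for differentiation the median was -0.01.

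For each comparison the 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1, 70 and 194 genes for differentiation, forskolin against vehicle and forskolin against undifferentiated cells, and 8, 317 and 1296 with the replicate block, and the highest other split gave 0 in each case. Of the others, 3 part all 3 same-numbered pairs as the real split does and 6 part 1 pair, and all of them gave 0. Each of them mixes the real groups, so real differences widen the spread within its groups. Their 0 calls therefore set no yardstick for the real counts.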
